A study of Mus musculus with 3 samples.

How the data were processed

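Single-cell RNA sequencing was done on forelimb buds of mouse embryos at embryonic day 9.5. Control embryos were homozygous for a floxed allele of Esco2, which encodes a cohesin acetyltransferase needed for sister chromatid cohesion. Mutant embryos also carried a Prrx1-Cre transgene, which deletes the floxed allele in limb bud mesenchyme. Libraries from 1 control and 2 mutant samples were used here. Per the labels, the design had 3 replicates per genotype, and a replicate joined 3 pooled samples of 2 limb buds each, 6 limb buds in all, from 2 male samples and 1 female sample. The sources used here do not say whether the replicates come from separate litters, so the p-values measure the spread between these libraries. Per the submitters' protocol, cells were released with trypsin, frozen in a cryoprotectant, thawed, pooled, strained and loaded for Chromium 3′ v3 chemistry.

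The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, and per the file headers they were written by Cell Ranger 7.0.0. Per the submitters' processing notes the genome build was mm10, and Seurat 4.0.0 was also used, in a role not given in the sources used here. The annotation release, the handling of intronic reads and the calling of cells are not given in the sources used here either. Every matrix has 31054 features, of which 31053 are Ensembl genes and 1 is named CRE. The values are whole numbers, and no normalisation had been applied. The matrix of the control library held 6527 barcodes with 202581488 UMIs, that of mutant 1 held 7219 barcodes with 178159788 UMIs, and that of mutant 2 held 8755 barcodes with 225032823 UMIs.

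Barcodes were kept with at least 500 genes detected and under 10% mitochondrial UMIs. Of the barcodes of control 1, mutant 1 and mutant 2, 997, 1647 and 1550 had too few genes, and 1441, 1886 and 2399 others had too high a mitochondrial share. Scrublet, run per library through scanpy 1.11.5 with an expected rate of 0.06, called 35, 90 and 125 doublets, which were removed. The 12331 remaining cells were 4054 of control 1, 3596 of mutant 1 and 4681 of mutant 2. Their median depths were 22877, 36245 and 41477 UMIs. The 3 libraries were clustered together without integration, from 2000 variable genes, 30 principal components and 15 nearest neighbours, with the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0, which gave 26 clusters. The work used Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.

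Clusters were named from 13 lists of marker genes. A marker counted for a cluster at 20 or more CPM, the UMIs of a gene scaled to a fixed total, and at a log2 ratio of at least 1 over the median cluster, with an offset of 5 CPM. A cluster took the name of the list with the largest share of its markers so raised, at least 3, or of a list with more markers among the cluster's 10 most raised genes. Clusters whose median depth fell under 33.3% of the library median stayed unnamed unless a marker of their class was among those 10 genes. The limits of this naming rule were set after the clusters were seen, and the marker lists before. The 5 classes with at least 50 cells in every library were compared: limb mesenchyme, surface ectoderm with the apical ridge, endothelium, primitive erythroid cells, and flank and visceral lateral plate mesoderm. The names describe marker expression, and no sort or gate had selected these cells.

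UMIs were summed per library over the cells of a class. Differences between mutant and control sums were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM factors) on genes with a mean of at least 5 CPM, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. This fit has 1 residual degree of freedom, so the spread comes from the 2 mutant libraries and the lone control is assumed to vary like them. Whether the mutant effect differed between mesenchyme and ectoderm was tested with an edgeR interaction term on the 6 sums, with a term for each library, again with 1 residual degree of freedom. Log2 CPM values used a prior count of 2. CPM values given for tested genes were scaled by the UMIs of all tested genes and by the TMM factors. For genes under the mean of 5 CPM and for summed cell type markers, all UMIs of the class were the total, without these factors. Sums ranged from 7809207 UMIs in flank cells of mutant 2 to 103494313 UMIs in mesenchyme of mutant 2. The cell filter, the clustering, the tests, the lists of genes and 63 alternatives were fixed before the data were examined. An exact permutation of 1 control against 2 mutants cannot give a p below 0.333, so shares of cells are given without a test, with exact Clopper-Pearson 95% intervals. These intervals, and upper limits drawn from 3 counts where a share is 0, cover counting error only.

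Lists of genes, 23 in number, were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. The median log2 fold of a list was set against 10000 random lists matched on expression. Counts of called members are given over all genes tested and adjusted over the list alone. Cells were scored for cell cycle phase, and the share of cells with a UMI of a gene was measured, after thinning each cell to 10000 UMIs, with shallower cells left out. The balance of chromosomes in single cells was estimated from 28944 genes on 19 autosomes. These genes leave out those called in mesenchyme and haemoglobin genes. Each autosome's share of a thinned cell's UMIs was set against the mean share in the cell's cluster and library, for clusters with at least 10 cells there. A chromosome with at least 200 expected UMIs was called off at a deviation of at least 35%.

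The rule for genes to name was set in advance. It takes 14 genes of interest in mesenchyme, namely Esco2, Esco1, Smc3, Prrx1, Cdkn1a, Mdm2, Ccng1, Trp53inp1, Bax, Phlda3, Pmaip1, Trp53, Vegfa and Fgf10. It adds up to 10 higher and 10 lower called genes with a mean of at least 20 CPM and the same sign in both mutants, ranked by the smaller of their 2 log2 folds. For other classes and the interaction it adds 3 in each direction, and per list up to 4 called members, or 2 uncalled members where none was called. Xist, Tsix, Y-linked, haemoglobin and mitochondrial genes and unnamed gene models were left out of this ranking. Positions come from a GENCODE annotation of GRCm38, in which 30934 of the features were found.

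The test was tried on simulated counts with 50 changed genes per fold and the common dispersion of each comparison. In mesenchyme it called 4% of genes changed by 1.5-fold, 30% of those changed by 2-fold and 98% of those changed by 4-fold, with 0 of the unchanged genes called. For ectoderm, endothelium, erythroid cells and flank, 98%, 100%, 100% and 76% of the 4-fold changes were called, and for the interaction 96%. The same simulation called 3, 8, 6, 3 and 8 unchanged genes in these 5 comparisons. It gives every gene the same dispersion, as the mesenchyme and interaction fits have it. With dispersions that differ between genes by the prior df of the fit, 70% of 4-fold and 86% of 8-fold changes were called in ectoderm, with 18 unchanged genes, and none of either in endothelium, erythroid cells and flank, so 0 calls there do not show that genes were unchanged. A simulated list of 30 genes shifted by 1 on the log2 scale was called by camera with the preset correlation, and was missed with the estimated correlation and by fry. A call lost with either of these, in any comparison below, therefore does not show that a list was unchanged.

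Alternatives to the main settings covered DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, limma-voom, other filters on low counts, kept doublets, stricter cell filters, a lower clustering resolution of 0.5, thinned sums, cells of 1 sex, and each mutant library left out. Alternatives added after the data were seen split the mesenchyme by phase or by cluster, exchanged the reference class of the interaction, gave every fit a shared spread or the prior df of ectoderm, or changed the denominator of the shares or the clusters counted as mesenchyme. Removed barcodes were used only for the levels of 6 features. The macrophage, myogenic and coelomic classes had too few cells in at least 1 library for a test of genes.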

Results

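Esco2 (ENSMUSG00000022034, GRCm38 chromosome 14, 65819038 to 65833994) stood at 32.4 CPM in the mesenchyme of control 1, at 23.1 CPM in mutant 1 and at 22.5 CPM in mutant 2. Its log2 fold of the mutants over the control was -0.51 (SE 0.26), which the edgeR fit did not call (adjusted p = 0.956). After thinning to equal depth, 26.6% of mesenchyme cells of control 1 had an Esco2 UMI, against 20.4% in mutant 1 and 20.2% in mutant 2. Erythroid cells, in which Prrx1-Cre is not active, had an Esco2 UMI in 20.8%, 20.8% and 22.1% of cells. Without thinning these shares were 76.7%, 53.2% and 57.6% in mesenchyme, at median depths of 75256, 38108 and 54599 UMIs. In erythroid cells they were 67.6%, 63.7% and 59.0%, at median depths of 87554, 63780 and 58323 UMIs. The reads come from the 3′ ends of transcripts and the deleted part of the gene is not given in the sources used here, so these values do not measure the deletion. UMIs of the CRE feature were found in 0 of 584 mesenchyme cells of control 1, which allows a share of up to 0.514%. They were found in 5.18% of mesenchyme cells of mutant 1 (95% interval 3.93% to 6.69%) and in 6.32% of mutant 2 (5.28% to 7.50%), and in 0.163% and 0 of 480 of their erythroid cells (up to 0.625%). At equal depth the mesenchyme shares were 0, 0.305% and 0.542%. Flank cells of the mutants also held CRE UMIs, with 12 in flank cluster 18, against 0 of 258 flank cells of control 1. Flank is therefore not a class free of Cre.

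Mesenchyme cells, marked by Prrx1, Tbx5 and Twist1, made up 14.4% of the kept cells of control 1 (95% interval 13.3% to 15.5%), 29.5% of mutant 1 (28.0% to 31.0%) and 41.2% of mutant 2 (39.8% to 42.7%). Endothelial cells were 19.5% of control 1 (18.3% to 20.8%), 13.2% of mutant 1 (12.1% to 14.4%) and 10.5% of mutant 2 (9.63% to 11.4%). A shallow endothelial cluster held 7.87%, 2.45% and 1.47% of the kept cells in the same order, so much of this difference lies in shallow cells. With the stricter cell filter, which changes the denominator as well, endothelium was 20.4%, 15.2% and 11.0%. Myogenic progenitors were 1.21%, 5.39% and 9.70% of the kept cells in the same order. Surface ectoderm was 8.46%, 12.3% and 6.64%, with the mutants on either side of the control. Erythroid cells were 11.0%, 17.1% and 10.3%, flank cells 6.36%, 6.34% and 4.61%, coelomic cells 0.469%, 0.0278% and 2.41%, and macrophages 0.518%, 0.473% and 0.919%. Unnamed cells were 38.1% of control 1, 15.6% of mutant 1 and 13.7% of mutant 2. Among them were 5 clusters, shallow in at least 1 library, whose best marker list was that of limb mesenchyme. They held 37.2%, 15.5% and 13.7% of the cells of the 3 libraries. Counted with these clusters, mesenchyme was 51.6% of control 1, 45.1% of mutant 1 and 54.9% of mutant 2, so the difference in its share depends on their naming. Of these clusters, cluster 6 (2, 19 and 38 cells) and cluster 24 (1, 49 and 85 cells) were nearly absent from control 1. Cluster 6 was led by Cdkn1a, Phlda3 and Ccng1, and Ano3 was among the 10 most raised genes of cluster 24. Their cells were left out of the mesenchyme class and so of its share of cells with a Cdkn1a UMI. With 1 control library no difference in shares can pass an exact permutation test, whose smallest p is 0.333.

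**Figure D1:**
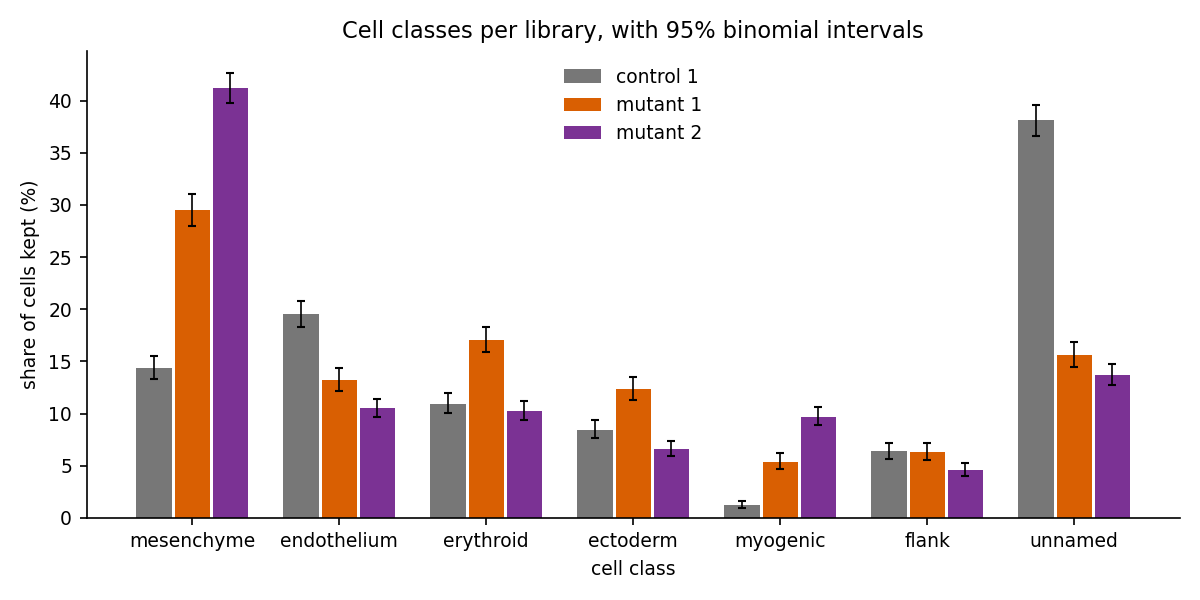
Share of the kept cells (percent, vertical axis) in each cell class (horizontal axis) for control 1, mutant 1 and mutant 2, with bars for the share and error bars for exact 95% binomial intervals. Mesenchyme stands at 14.4% in control 1 and at 29.5% and 41.2% in the mutants, and unnamed cells at 38.1% against 15.6% and 13.7%.

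In mesenchyme, genes that p53 activates were among those that rose. The edgeR fit tested 10153 genes and called 99 higher and 55 lower in the mutants, and without a mesenchyme cluster that control 1 lacked it called 20 higher and 44 lower. This fit gave all genes a shared spread (an infinite prior df), where those of the other 4 classes let the spread differ between genes (prior df 2.26 to 4.10). With the prior df of the ectoderm fit, 4.10, it called 0 genes, with 256 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0548, that of Cdkn1a. Counts of called genes are therefore not compared between classes. Cdkn1a (ENSMUSG00000023067, GRCm38 chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, rose from 1.40 CPM in control 1 to 69.3 CPM in mutant 1 and 71.2 CPM in mutant 2 (log2 fold 5.65, SE 0.41, adjusted p = 1.72e-38). Ano3 (ENSMUSG00000074968, chromosome 2, 110655201 to 110950923), which encodes a membrane protein of the anoctamin family, rose from 1.12 to 86.5 and 67.6 CPM (log2 fold 6.10, SE 0.44, adjusted p = 1.07e-40). Ccng1 (ENSMUSG00000020326, chromosome 11, 40748552 to 40755311) rose from 6.51 to 46.1 and 46.3 CPM (log2 fold 2.83, SE 0.31). Trp53inp1 (ENSMUSG00000028211, chromosome 4, 11156431 to 11174379) rose from 1.51 to 20.3 and 18.8 CPM (log2 fold 3.69, SE 0.35). The receptor phosphatase gene Ptprt rose by 3.41 on the log2 scale, Samd12 by 3.36, Cyyr1 by 2.36, Rb1 by 1.49 and Ptpn14 by 1.39. Shox2 (ENSMUSG00000027833, chromosome 3, 66971727 to 66981771), a regulator of proximal limb outgrowth, rose from 17.3 to 40.4 and 47.5 CPM (log2 fold 1.34, adjusted p = 0.000529).

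Among the lower genes were single members of the BMP and WNT lists, and neither list was called (camera adjusted p = 0.237 and 0.0751). Msx2 (ENSMUSG00000021469, chromosome 13, 53466884 to 53473074), a transcription factor downstream of BMP signals, fell from 51.6 CPM to 24.8 and 29.4 CPM (log2 fold -0.93, SE 0.26, edgeR adjusted p = 0.0315). The WNT feedback inhibitor Nkd1 fell from 100.4 CPM to 59.8 and 37.2 CPM (log2 fold -1.05, adjusted p = 0.0370). The ligand gene Wnt2 had a log2 fold of -0.97, with -0.50 in mutant 1 and -1.64 in mutant 2. Ppp2r2b (-1.21, with -0.59 and -2.32) and Nebl (-1.07, with -0.63 and -1.68) also differed more in mutant 2. Opcml had a log2 fold of -1.26, Dqx1 of -1.12, Gstp1 of -1.09 and Plaur of -0.98. Markers of flank mesoderm summed to 68.2 CPM in the mesenchyme of control 1 and to 43.0 and 19.2 CPM in the mutants. Eif3j2 rose by 2.67 and Hist1h2ap fell by 1.31 on the log2 scale, and both moved the same way in all 5 classes compared. Of the 60-base words of their 3′ ends, 82.4% and 100% also occur in another gene, so these 2 values are not read as mutant effects.

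Of the remaining genes of interest, Phlda3 rose (log2 fold 1.31, edgeR adjusted p = 0.000468), and Mdm2 was not called (log2 fold 1.06, SE 0.34, adjusted p = 0.0943), with 44.9 CPM in control 1, 96.3 CPM in mutant 1 and 91.3 CPM in mutant 2. Bax (0.36), Trp53 (-0.07), Smc3 (0.06), Esco1 (-0.07), Prrx1 (0.24), Vegfa (-0.36) and Fgf10 (-0.17) were not called. The BH3-only gene Pmaip1 stayed under the mean of 5 CPM, with 0.847, 4.64 and 7.41 CPM. DESeq2 called 69 genes in place of 154, of which 66 were shared, and 370 genes were called when the limit on low counts was lowered to a mean of 1 CPM. One mesenchyme cluster had no cells of control 1, 149 of mutant 1 and 202 of mutant 2, and its definition follows the difference measured. Without it 64 genes were called, 62 of them shared, the log2 fold of Cdkn1a was 2.32 and that of Ccng1 1.22, and Phlda3 moved to -0.08. Of the other clusters the largest part of the mesenchyme came from cluster 9 in control 1 and mutant 1 (38.5% and 41.2% of the class) and from cluster 12 in mutant 2 (54.8%).

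**Figure D2:**
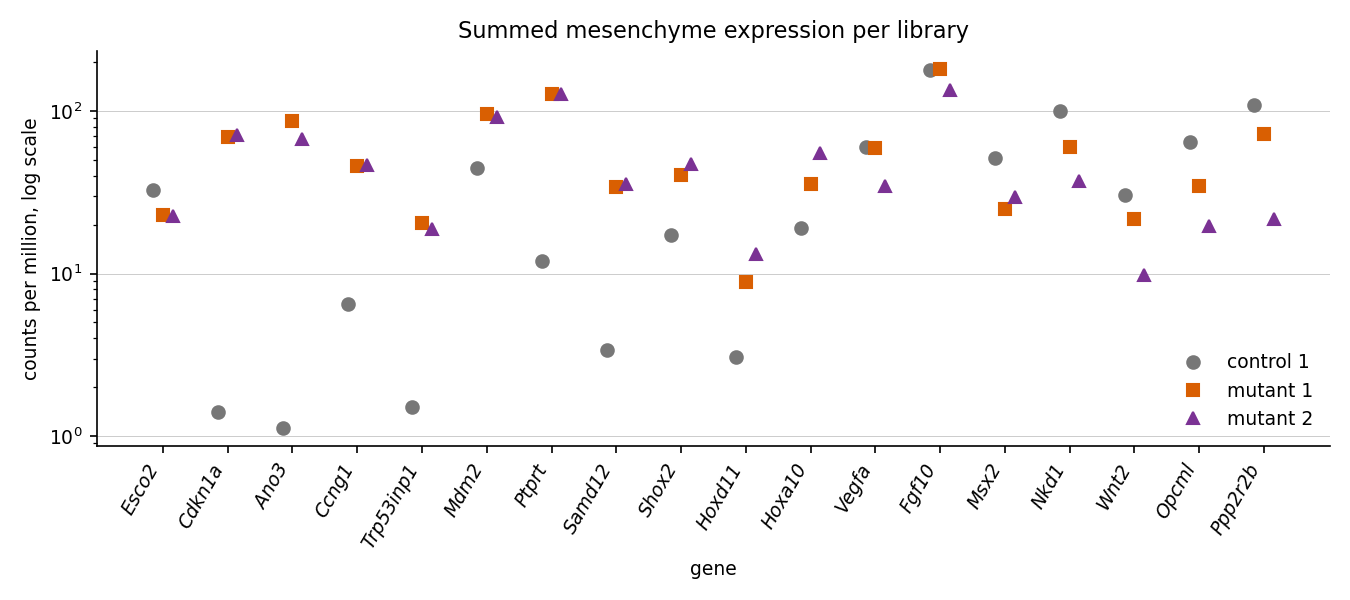
Summed mesenchyme expression (CPM on a log axis) of named genes (horizontal axis), with 1 point each for control 1, mutant 1 and mutant 2. Cdkn1a lies at 1.40 in control 1 and at 69.3 and 71.2 in the mutants, while Ppp2r2b lies at 109 in control 1 and at 72.7 and 21.8.

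Of the 30 tested members of the p53 target list 13 rose in mesenchyme and none fell over all genes, and 18 rose adjusted over the list alone. The median log2 fold was 0.91, at 0.96 in mutant 1 and 0.81 in mutant 2, and 27 members were positive. Camera called the list higher (adjusted p = 1.07e-91), and the call did not hold with an estimated correlation (adjusted p = 0.623) or with fry (adjusted p = 0.40). Both also missed the simulated list of 30 shifted genes, so these lost calls decide nothing. With a spread shared by all genes in every class, 13 of 30 members tested were higher in mesenchyme and 1 of 30 in ectoderm. In endothelium 1 of 24 was higher, in erythroid cells 0 of 14 and in flank 0 of 26. At this setting 3 members were lower in ectoderm, 2 in endothelium, 1 in erythroid cells and 0 in mesenchyme and flank. Cdkn1a was itself among the genes called in endothelium. With the prior df of ectoderm none was called, and 17 were higher at an unadjusted p under 0.05 in mesenchyme, against 1 in ectoderm, 1 in endothelium, 0 in erythroid cells and 1 in flank. Without the cluster that control 1 lacked, the median over 24 members was 0.13 (camera adjusted p = 0.00148). Ddit4l (ENSMUSG00000046818, chromosome 3, 137621612 to 137628333), an inhibitor of mTOR, rose from 0.302 to 21.5 and 18.7 CPM (log2 fold 6.05, edgeR adjusted p = 4.40e-42). Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216), a receptor of the TNF receptor family, rose by 3.66 on the log2 scale, with Cdkn1a and Trp53inp1 between them in order of p. Bbc3 (0.84) and Bax (0.36), which promote cell death, were uncalled. Genes of the apoptosis machinery as a list had 1 of 17 members higher, Apaf1 at 1.02 (edgeR adjusted p = 0.0297), and a median of 0.12 (camera adjusted p = 0.237).

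**Figure D3:**
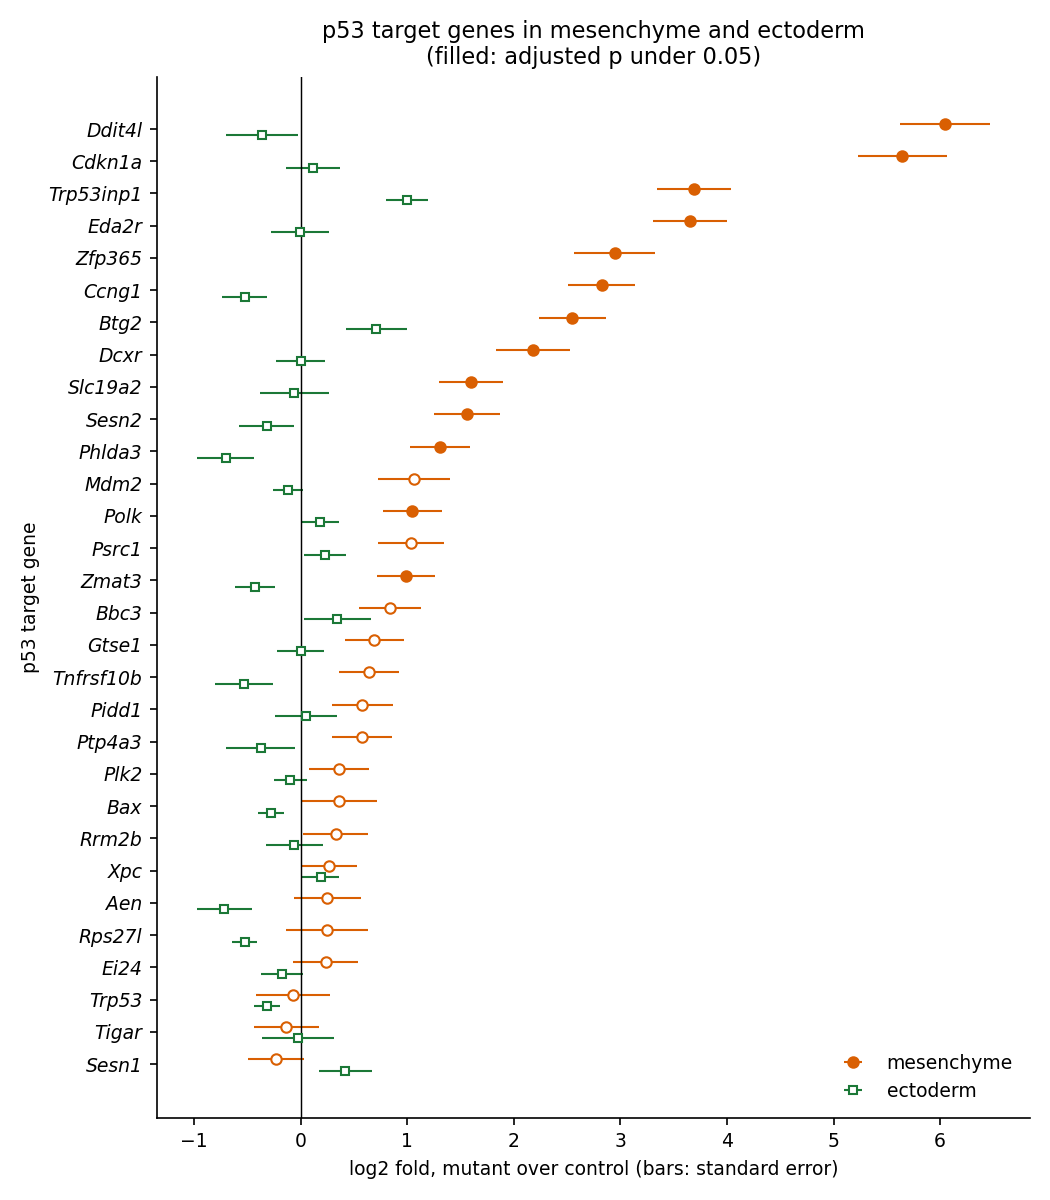
Log2 fold of the mutants over the control (horizontal axis) for each p53 target gene tested in mesenchyme (vertical axis), with points for mesenchyme and ectoderm and bars for the standard error of the edgeR fit. Ddit4l (6.05) and Cdkn1a (5.65) lead in mesenchyme, and filled points mark the 13 genes called there.

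No proliferation, cohesin or repair list was called in mesenchyme. The S phase list had 0 of 43 members called and a median log2 fold of -0.04 (camera adjusted p = 0.500), with Pcna at -0.60 and Ung at -0.31. The G2/M list had 0 of 54 called, 43 positive and a median of 0.08 (adjusted p = 0.224), with Psrc1 at 1.03 and Gtse1 at 0.69, and the spindle checkpoint list 0 of 24 and 0.05 (adjusted p = 0.758), with Cenpe and Cenpf at 0.36. The cohesin list had 0 of 18 called (adjusted p = 0.812), with a median of 0.01 where its mean (-0.02) and its test pointed down, and Cdca5 at 0.20. The DNA damage list had 0 of 24 called (adjusted p = 0.929), with Mre11a at -0.27 and Rad50 at 0.28, and with a median of 0.01 where the test pointed down.

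Lists of signals to vessels were not called in mesenchyme by the main settings, and 2 of them were by some alternatives. The hypoxia list had a median of -0.06 (25 genes, camera adjusted p = 0.194), with 0.34 in mutant 1 and -0.53 in mutant 2, and 4 alternatives called it lower (adjusted p = 0.00707 to 0.0429). In the few cells with Xist and no Y-linked UMI camera called the hypoxia list higher. Its member Ddit4 rose by 1.32 on the log2 scale (edgeR adjusted p = 0.000899), with 1.79 in mutant 1 and 0.61 in mutant 2. The angiogenic ligands had 0 of 12 called (adjusted p = 0.758), with a median of 0.05 (0.15 in mutant 1 and -0.21 in mutant 2) where mean and test pointed down, Sema3c at -0.55 and Vegfc at -0.38. In the list of endothelial specification (9 genes, median 0.16, adjusted p = 0.0601, called higher by 5 alternatives at 0.00581 to 0.0472), Notch1 rose from 2.46 CPM in control 1 to 10.7 and 10.2 CPM (log2 fold 2.08, edgeR adjusted p = 2.28e-07).

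Limb patterning lists were not called either, although single genes in them rose or fell. Hoxd11 rose by 1.84 (edgeR adjusted p = 5.09e-06) and Hoxa10 by 1.25 (adjusted p = 0.00231) on the log2 scale. Of the 17 limb Hox genes these were the 2 called, and 3 rose and 2 fell adjusted over the list alone. The median of the Hox list was -0.27 where its mean (0.05) and camera pointed up (adjusted p = 0.889). Cyp26b1, which degrades retinoic acid, rose by 1.61 (edgeR adjusted p = 0.000203), in a list of proximodistal genes with a median of -0.0039 and a mean of 0.10 (11 genes, camera adjusted p = 0.752). The FGF list had 10 of 12 members positive and a median of 0.24 (adjusted p = 0.237), with Dusp6 at 0.46 and Il17rd at 0.43. The Hedgehog list had a median of -0.06 and a mean of 0.09 (8 genes, adjusted p = 0.758), with Grem1 at 0.86 and Ptch1 at 0.69. The BMP list, through Msx2, had 1 of 13 lower and a median of -0.22 (adjusted p = 0.237), and the WNT list, through Nkd1, 1 of 12 lower and a median of -0.20 (adjusted p = 0.0751). Adjusted over the list alone, 2 BMP genes and 3 WNT genes fell and 1 BMP gene rose. The limb identity list had a median of -0.05 (19 genes, adjusted p = 0.752) and the chondrogenesis list of 0.14 (9 genes, adjusted p = 0.758), with Sox9 at 0.86 and Col1a1 at -0.78, both uncalled.

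Among stress lists in mesenchyme, immediate early genes of tissue dissociation were called higher (12 genes, median 0.46, camera adjusted p = 0.0170). The dissociation list kept this direction and lost the call in 8 alternatives, among them the estimated correlation (adjusted p = 0.940). Their median was -0.12 without mutant replicate 2, and without the cluster that control 1 lacked camera pointed down (adjusted p = 0.853). Of this list Btg2, which is also a p53 target, rose by 2.55 on the log2 scale, and Fos rose by 1.06, with -0.55 in mutant 1 and 1.79 in mutant 2. Ribosome biogenesis had 3 of 24 members positive and a median of -0.13 (adjusted p = 0.194), with Rrs1 at -0.72 and Nop2 at -0.26. The list of the integrated stress response had a median of -0.01 and a mean of 0.12 (16 genes, adjusted p = 0.449), and in it Sesn2 rose by 1.56. Necroptosis and clearance had a median of -0.04 (6 genes, adjusted p = 0.911), with Mertk at 0.34 and Ripk1 at -0.25. The interferon list had 2 tested genes and a median of -0.37 (adjusted p = 0.237), and in it Stat2 had a log2 fold of -1.36 (edgeR adjusted p = 0.000211).

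The medians of the lists were also set against 10000 random lists matched on expression, which ignore correlation between members. In mesenchyme the medians of the p53, dissociation and G2/M lists lay at percentile 100 of the random lists and that of the FGF list at 99.99, and those of the Hox (0), BMP (0.01), ribosome biogenesis (0.01) and WNT (0.05) lists at the low end. Of these 8 lists camera called the p53 and dissociation lists alone. In flank the hypoxia, proximodistal and chondrogenesis medians lay at percentile 100 and that of the angiogenic ligands at 99.96, and in erythroid cells that of the dissociation list at 0.01, all uncalled by camera.

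A minority of mutant mesenchyme cells held the Cdkn1a signal. At equal depth, 1.08% of mesenchyme cells of control 1 had a Cdkn1a UMI (95% interval 0.396% to 2.33%), against 13.95% of mutant 1 (11.8% to 16.3%) and 13.3% of mutant 2 (11.8% to 14.9%). Erythroid cells, which serve as the background, had one in 2.76%, 1.34% and 2.93% of cells. Ectoderm cells had one in 31.7%, 25.9% and 32.2%, endothelial cells in 5.61%, 10.6% and 4.24%, and flank cells in 2.03%, 6.05% and 2.45%. Without thinning the mesenchyme shares were 2.91%, 18.3% and 18.4% at median depths of 75256, 38108 and 54599 UMIs, and the erythroid shares 6.08%, 4.72% and 6.88% at 87554, 63780 and 58323 UMIs. Mesenchyme cells scored as S phase were 36.8% of control 1, 29.0% of mutant 1 and 29.3% of mutant 2, and cells scored as G2/M were 62.7%, 70.2% and 70.2%. In ectoderm S phase shares were 31.7%, 29.6% and 29.5%, and G2/M shares 62.4%, 62.0% and 54.0%. Free RNA enters phase scores as well. With doublets kept and the cells clustered anew, which moved most flank cells into mesenchyme (789 in place of 584 cells in control 1), the mutant mean of the S phase share lay 3.12 points below the control in place of 7.66 points.

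**Figure D4:**
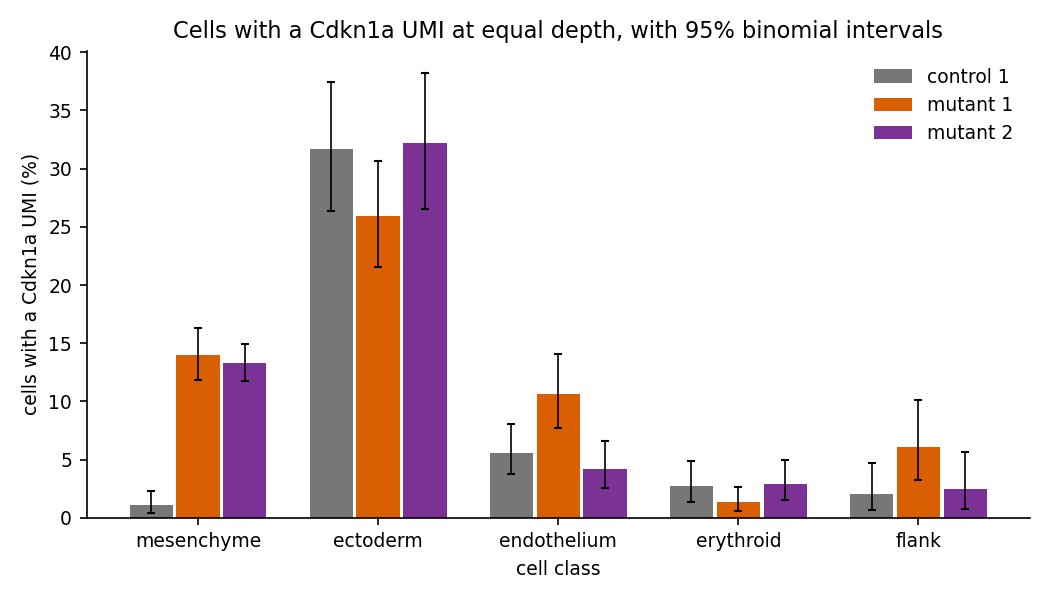
Share of cells with a Cdkn1a UMI (percent, vertical axis) after thinning to 10000 UMIs per cell, by cell class (horizontal axis) and library, with error bars for exact 95% binomial intervals. Mesenchyme lies at 1.08% in control 1 and at 13.95% and 13.3% in the mutants, and ectoderm lies at 25.9% to 32.2% in all libraries.

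In ectoderm no single gene was called, and camera called 4 lists, none of which held with an estimated correlation (adjusted p = 0.992 for each). Of 10642 genes edgeR called 0, with 1226 at an unadjusted p under 0.05, DESeq2 called 37, and edgeR with a spread shared by all genes 1034. Ribosome biogenesis genes had a median log2 fold of -0.41 with 0 of 24 positive (camera adjusted p = 8.03e-07), with Ncl at -0.63 and Nhp2 at -0.73. S phase genes had a median of -0.23 with 4 of 43 positive (adjusted p = 1.85e-05), with Pcna at -0.93. The BMP list (median -0.14, adjusted p = 0.0497) was also called lower, with 5 members lower adjusted over the list alone, and the chondrogenesis list (median 0.38, adjusted p = 0.0207) higher, with Runx1 at 1.61. The p53 list did not move in ectoderm (median -0.06, 30 genes, adjusted p = 0.510). Cdkn1a stood at 51.0, 45.2 and 65.7 CPM in ectoderm. Cluster 3 held 74.9%, 75% and 64.3% of the ectoderm class, cluster 23, with a higher mitochondrial share, 8.75%, 19.6% and 24.8%, and a shallow cluster 16.3%, 5.41% and 10.9%. Cluster 23, led by Fgf8 and Adamts18, held 5.57%, 16.8% and 21.1% of the ectoderm UMIs.

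The mutant effect differed between mesenchyme and ectoderm for 189 of 10629 genes in the edgeR interaction test, 100 higher and 89 lower in mesenchyme. This fit also shared the spread among all genes, and with the prior df of the ectoderm fit it called 0, with 294 at an unadjusted p under 0.05. DESeq2 called 39, and without the cluster that control 1 lacked edgeR called 26 higher and 86 lower. The smallest p-values were those of Ano3 (log2 difference 6.39, SE 0.39, edgeR adjusted p = 6.29e-57) and Cdkn1a (5.53, SE 0.35, adjusted p = 1.36e-52). Mdm2 passed this test (1.16, adjusted p = 0.0114), as did Sox9 (1.14, adjusted p = 0.010). The p53 list had 14 of 30 members higher and a median difference of 0.95 (camera adjusted p = 7.34e-62), which did not hold with an estimated correlation (adjusted p = 0.763). Set against endothelium in place of ectoderm, 15 of 28 p53 members were higher with a median of 0.94, and against erythroid cells 14 of 28 with a median of 0.92. Against flank mesoderm edgeR called 0 of 10462 genes at a prior df of 3.77, with 333 at an unadjusted p under 0.05, and the p53 median was 0.74. Flank cells of the mutants held CRE UMIs, so this reference is not free of Cre. Rspo2, which encodes a WNT agonist, had a difference of -3.25 (SE 0.36, adjusted p = 8.23e-17), carried by ectoderm, where it stood at 30.7 CPM in control 1 and at 165 and 218 CPM in the mutants. Zeb2 had a difference of -2.003 (adjusted p = 4.19e-08).

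Krt7 and Hoxd10 were called in the interaction on few UMIs. Mesenchyme of control 1 had 1 UMI of Krt7, an epithelial keratin gene (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313), against 80 in mutant 1 and 137 in mutant 2. The ratios to the control were 73.7 (95% interval 12.9 to 2947) and 62.5 (11.0 to 2486). Ectoderm of control 1 had 0 UMIs of Hoxd10, against 5 in mutant 1 and 13 in mutant 2, so its level there was at least 1.95-fold and 9.82-fold higher, against a floor of 3 UMIs per library.

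In endothelium no single gene was called, and camera called 7 lists, none of which held with an estimated correlation (adjusted p = 0.688 for each). Of 9753 genes edgeR called 0, with 684 at an unadjusted p under 0.05, DESeq2 called 48, and edgeR with a shared spread 1058. The G2/M list was called higher (median 0.13, 46 of 54 positive, camera adjusted p = 0.000108), with Cenpf at 0.51 and Nusap1 at 0.48, as was the spindle checkpoint list (median 0.11, 21 of 24 positive, adjusted p = 0.00998). Proximodistal genes (8 of 8 positive, median 0.36, adjusted p = 0.00444) and chondrogenesis genes (4 tested, median 0.94, adjusted p = 0.00436), with Sox5 at 1.97 and Sox6 at 1.76, were also called higher. Ribosome biogenesis (median -0.33, 1 of 24 positive, adjusted p = 1.42e-09), the integrated stress response (-0.25, adjusted p = 0.00998) and dissociation genes (-0.27, adjusted p = 0.0299) were called lower. Endothelial specification genes as a list were not called (28 genes, 19 positive, median 0.06, adjusted p = 0.306). The arterial connexin gene Gja5 stood at 1.88 CPM in control 1 and at 8.18 and 14.4 CPM in the mutants (log2 fold 2.58, SE 0.49), and Gja4 at 41.5, 66.5 and 68.0 CPM (log2 fold 0.70), both uncalled (edgeR adjusted p = 0.679). One shallow endothelial cluster held 40.3% of the class in control 1, 18.5% in mutant 1 and 14.1% in mutant 2, and the largest part came from cluster 4 in mutant 1 (47.4%) and mutant 2 (56.8%) and, at 40.5%, in control 1.

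In erythroid cells edgeR called 0 of 7250 genes, with 183 at an unadjusted p under 0.05, DESeq2 called 22, and edgeR with a shared spread 276. DNA damage genes (18 of 23 positive, median 0.11, camera adjusted p = 0.0328) and 3 proximodistal genes led by Meis2 (median 0.90, adjusted p = 0.0328) were called higher, and with an estimated correlation neither was (adjusted p = 0.904). In flank mesoderm edgeR called 0 of 10535 genes, with 203 at an unadjusted p under 0.05, DESeq2 called 4, and edgeR with a shared spread 195. FGF targets in flank were higher as a list (9 of 10 positive, median 0.33, adjusted p = 0.0168), and BMP genes (median -0.33, adjusted p = 0.0319) and WNT genes (median -0.39, adjusted p = 0.00433) lower, with Rspo3 at -1.64 and Msx1 at -1.06. None of these 3 calls held with an estimated correlation (adjusted p = 0.805). The p53 list was not called in erythroid cells (median -0.11) or in flank (median 0.04). Cluster 18 held 82.2%, 100% and 62.5% of the flank class, and cluster 8 held 56.8%, 61.7% and 49.2% of the erythroid class.

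Mesenchyme differed between the mutant libraries as much as from the control. By a log2 difference above 0.5, 851 genes differed between mutant 1 and control 1, 1095 between mutant 2 and control 1, and 1134 between mutant 2 and mutant 1. Xist fell by 4.39 on the log2 scale in mutant mesenchyme. Of the named cells outside the erythroid class, 12.5% in control 1 had Xist and no Y-linked UMI, against 1.16% in mutant 1 and 1.77% in mutant 2, and 64.0%, 91.9% and 89.5% had a Y-linked UMI and no Xist. Samples with equal numbers of cells, 1 female in 3, would give more cells with Xist than the mutants had. The mutant shares therefore go against the stated pools. Cells with both kinds of UMI or with neither are not in these shares, so those of control 1 leave this open. Among mesenchyme cells with a Y-linked UMI and no Xist UMI the median log2 fold of the p53 list was 0.90. The 95, 13 and 13 mesenchyme cells with Xist and no Y-linked UMI gave log2 folds of the opposite sign for Shox2 (-1.29), Msx2 (1.06), Nkd1 (1.15), Cyyr1 (-0.46) and Mdm2 (-0.19).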

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

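The tests of a whole-library difference, of the sexes and of the lone control for the p53 genes, of the cluster mix for the lower genes and of their calls in the interaction, and of mesenchyme RNA in ectoderm were chosen only after the results were seen. The differences in this part came up because the mutant effect in mesenchyme was unlike that in ectoderm of the same libraries. The edgeR interaction test gave this for 189 genes, or 0 with the prior df of the ectoderm fit. Camera gave it for 5 lists, none of which was called with an estimated correlation (smallest adjusted p = 0.763). That setting also missed a simulated shifted list, so these lost calls decide nothing.

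p53 target genes differed by a median log2 difference of 0.95, with Cdkn1a at 5.53, Ccng1 at 3.34, Trp53inp1 at 2.68, Phlda3 at 2.01 and Mdm2 at 1.16. A difference of the whole library would shift the list alike in ectoderm, and the quartiles of the difference, 0.49 and 1.86, both lie above 0. RNA from surface ectoderm, where Cdkn1a is abundant, would bring its markers along, yet their median log2 fold in mesenchyme was 0.31 and their levels imply 0.405% and 0.256% ectoderm RNA, where Cdkn1a would need 156% and 103%. Female cells in control 1 do not account for it either, since cells with a Y-linked and no Xist UMI gave a median of 0.90. Whether mesenchyme of other control embryos would resemble control 1 cannot be told apart from the genotype, because there is 1 control library, and the exact permutation, whose p cannot fall below 0.333, decides nothing, so a response to the loss of Esco2 stays a hypothesis.

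For the marker test an offset of 1 CPM was added after 0 of the 14 ectoderm markers passed the expression limit, before its value was seen, and Perp, a p53 target, was left out of the levels summed over 13 markers.

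The 55 genes lower in mutant mesenchyme had a median log2 fold of -1.16. With the same mix of mesenchyme clusters in every library 54 of them had a median of -1.12, which is 96.5% of that size. The cluster that control 1 lacked was counted there as part of cluster 12. The kept size argues against the mix of these clusters as the cause. It does not show that the folds would recur, as the genes were chosen on the same 584 control cells. On the fewer cells left, and at a prior df of 7.68 in place of an infinite one, 12 were still called. The median log2 difference of the lower genes to ectoderm was -0.92 (48 genes, quartiles -1.77 and -0.26) with a median of -0.54 in ectoderm, and the difference set before as a bound decides nothing, because the genes were chosen by their mesenchyme fold. By the interaction test over all genes, 19 of the 48 had a lower mutant effect than in ectoderm. The false calls allowed among all 189 were 9.45. With the prior df of the ectoderm fit none of the 48 was called. A whole-library difference therefore cannot be told apart from one of mesenchyme for these genes. Opcml (-1.97), Nebl (-1.98) and Ppp2r2b (-2.65) had a lower mutant effect than in ectoderm by the interaction test. Flank markers stood at 68.2 CPM in control 1 and at 43.0 and 19.2 CPM in the mutants, so a different extent of the dissected tissue may contribute and was not tested further, and neither was an effect of genotype on position.

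The list of limb bud identity genes had a median log2 difference of -0.40 between mesenchyme and ectoderm, a call that, like that of the Hox list, did not hold with an estimated correlation (adjusted p = 0.878). Its 9 members that stood in control ectoderm under 10% of their mesenchyme level had a median of -1.28, and the other 10 members a median of 0.029. The same 9 members stood under 10% by the levels of the mutants. In ectoderm the 9 genes summed to 11.8 CPM in control 1 and to 25.1 and 32.3 CPM in the mutants, which is 0.837%, 1.62% and 2.12% of their mesenchyme level. This is consistent with more mesenchyme RNA in the ectoderm sums of the mutants. The limb Hox list (-0.61) split less clearly, with -0.80 for 9 members low in ectoderm and -0.36 for the other 6, so such RNA leaves part of it open.

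Among the other lists, chondrogenesis genes differed by -0.31 and ribosome biogenesis genes by 0.27, and with an estimated correlation neither was called (camera adjusted p = 0.878). Ano3 (6.39), Samd12 (2.73), Ptprt (2.37), Cyyr1 (1.48) and Ptpn14 (1.14) were more raised in mesenchyme than in ectoderm. The fitted difference of Krt7 (6.31) rests on 1 UMI in the mesenchyme of control 1, and that of Hoxd10 (-6.998) on 0 UMIs in its ectoderm. The mutant effect on Rspo2 (-3.25) and Zeb2 (-2.003) was lower in mesenchyme than in ectoderm because both stood higher in mutant than in control ectoderm. Whether the larger part of cluster 23 in the mutant ectoderm sums carries this was not tested.

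Barcodes removed for a high mitochondrial share held a signal above that of the control library for 4 genes. In CPM over genes outside the mitochondrial genome, Cdkn1a stood at 3.43 in the removed barcodes of control 1, at 25.9 in mutant 1 and at 25.4 in mutant 2. Ccng1 stood at 5.30, 30.5 and 24.8, and Ano3 at 4.64, 184 and 129. Mdm2 stood at 69.6, 132 and 141, although fewer of these barcodes had a UMI of it in the mutants, 25.1% and 22.8% against 28.3%.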

How the results depend on the processing

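The splits by phase and by cluster, the changes of prior df, the erythroid and flank references and the shares of named cells only or with the unnamed clusters were chosen after the data were seen, and the other alternatives before. Of 2101 values compared with an alternative, 1749 kept their direction and their side of the threshold or stayed within their spread. Another 141 kept the direction and lost the call, 36 gained one, 106 moved by more and 69 changed sign. For values with 1 mutant library left out, the spread was that between the 2 mutants. Dropping 1 of 2 libraries moves a mean by less than this spread. Such values stayed within it almost by construction, so their part of the 1749 shows no robustness. Leaving out 1 mutant library moved the difference in the share of mesenchyme from 15.1 to 26.8 points, of endothelium from -9.02 to -6.30, of ectoderm from -1.82 to 3.89, of S phase from -7.78 to -7.54, of G2/M from 7.51 to 7.59 and of cells with a Cdkn1a UMI from 12.2 to 12.9. It moved the median log2 fold of the p53 list in mesenchyme from 0.81 to 0.96 and of the G2/M list from 0.048 to 0.18. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Flank had no sums with doublets kept, and cells in G1 alone were too few for a fit, so these 2 alternatives gave no value. Unless a cause is named, the cause was not tested. With a spread shared by all genes edgeR called 154 genes in mesenchyme, 1034 in ectoderm, 1058 in endothelium, 276 in erythroid cells, 195 in flank and 189 in the interaction, and with the prior df of ectoderm 0 in each, so it rests on the moderation of the spread that edgeR called genes in no other class.

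DESeq2 called 69 genes in mesenchyme, 37 in ectoderm, 48 in endothelium, 22 in erythroid cells, 4 in flank and 39 in the interaction, where edgeR called 154, 0, 0, 0, 0 and 189. With a mean of at least 1 CPM, which tests more genes, 370 genes were called in mesenchyme and 309 in the interaction, and without a filter 695 and 297, with 638 in ectoderm and 238 in erythroid cells. Without a filter the prior df also became infinite in ectoderm and erythroid cells. It stayed finite in endothelium (5.16) and flank (7.69), where 0 genes were called. The flank reference gave 0 genes in the interaction. Without the cluster absent from the control, whose definition follows the outcome, 64 genes were called in mesenchyme and 112 in the interaction. Without the cluster with the highest mitochondrial share 82 were called, 68 higher and 14 lower, at a prior df of 7.31. With the same mix of clusters 28 were called, on fewer cells and at a prior df of 7.68. The main fit had an infinite prior df, so the fall from 154 in these last counts is not put down to the cells alone.

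Cells with Xist and no Y-linked UMI, of which the mutants had 13 each, gave 32 called genes and a changed sign for Esco1 (0.35), Prrx1 (-0.22), Mdm2 (-0.19), Phlda3 (-0.53), Trp53 (0.32), Vegfa (0.21), Eif3j2 (-1.04), Cyyr1 (-0.46), Shox2 (-1.29), Msx2 (1.06), Nkd1 (1.15), Ppp2r2b (1.51), Wnt2 (0.75), Ung (0.24), Cenpf (-0.00112), Dusp6 (-0.46), Il17rd (-0.14), Sox9 (-0.12), Nop2 (0.15), Mertk (-0.73) and Ripk1 (0.19). In other cells, Phlda3 changed sign without the cluster absent from the control (-0.078), Fgf10 without the cluster with the highest mitochondrial share (0.020), and, without a mutant replicate, Fos (-0.55 to 1.79) and the medians of the lists of dissociation (-0.12 to 0.60), hypoxia (-0.53 to 0.34), proximodistal genes (-0.29 to 0.18), angiogenic ligands (-0.21 to 0.15), limb identity (-0.14 to 0.18), Hedgehog (-0.19 to 0.096), spindle (-0.052 to 0.12), apoptosis (-0.0012 to 0.17), cohesin (-0.11 to 0.059), S phase (-0.12 to 0.042), integrated stress (-0.068 to 0.070) and DNA damage (-0.033 to 0.015).

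The median log2 fold of the p53 list was 0.79 with the stricter cell filter, 1.27 in S phase cells, 0.70 in G2/M cells, 0.13 without the cluster absent from the control, 1.13 without the cluster with the highest mitochondrial share, 0.67 with the same mix and 0.29 in the cells with Xist, where that of the S phase list was 0.12. The same mix still held cells of the cluster absent from the control, counted as part of cluster 12. The p53 list lost its camera call with an estimated correlation (adjusted p = 0.623), with fry (0.40) and in the cells with Xist (0.366). In those cells camera changed direction for apoptosis (0.474), S phase (0.366), DNA damage (0.792), hypoxia (5.56e-08), FGF (0.463), Hedgehog (0.421), Hox (0.421), BMP (0.423), WNT (0.474), chondrogenesis (0.526), integrated stress (0.839) and ribosome biogenesis (0.474). Other lists changed direction too, of which only the dissociation list had been called. With cells in G2/M only they were S phase, spindle and DNA damage (0.954 each), and with S phase only DNA damage (0.940), angiogenic ligands and Hedgehog (0.880), Hox (0.670) and necroptosis (0.915). Without the cluster absent from the control they were DNA damage (0.948), limb identity (0.985) and dissociation (0.853), while the G2/M list was then called higher (0.0218) and the interferon list lower (0.00148). Other calls were gained by the lists of endothelial specification, higher with male cells (0.0279), the stricter cell filter (0.0472), without the cluster with the highest mitochondrial share (0.0383), with a pair of the shallow clusters (0.00782) and with the same mix (0.00581), and of hypoxia, lower with male cells (0.0344) and in the last 3 of these (0.00707, 0.0429 and 0.0372). Ribosome biogenesis was lower in the same 3 (0.0172, 0.0429 and 0.00107), WNT with the stricter filter (0.0472) and in S phase cells (0.0196), and apoptosis was higher in S phase cells (5.99e-05) and without the cluster with the highest mitochondrial share (0.0383), and FGF with doublets kept (0.0243). Without the cluster with the highest mitochondrial share the lists that changed direction were spindle (0.917), DNA damage (0.785), Hox (0.607) and integrated stress (0.903), and with a pair of the shallow clusters spindle, angiogenic ligands and Hox (0.804), DNA damage (0.863) and necroptosis (0.936). With doublets kept they were DNA damage (0.740) and chondrogenesis (0.210), with the stricter cell filter DNA damage (0.848), with male cells DNA damage and Hox (0.915) and angiogenic ligands (0.951), and with the same mix DNA damage (0.924), angiogenic ligands (0.777) and Hox (0.418).

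The difference in the share of mesenchyme was -1.64 points with every unnamed cluster of mesenchyme markers added, and that of macrophages -0.647 at the lower resolution and -1.21 with the stricter cell filter. The difference in endothelium was -17.6 points among named cells only. That of S phase was -10.2 without thinning and -3.12 with doublets kept and cells clustered anew, which moved flank cells into mesenchyme, and that of G2/M 10.1 without thinning, 7.30 with lists free of p53 genes and 2.94 with doublets kept and cells clustered anew. That of cells with a Cdkn1a UMI was 15.5 without thinning. By a log2 difference above 1, 167, 287 and 218 genes differed between mutant 1 and control 1, mutant 2 and control 1, and the mutants.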

Other observations

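The comparison of gene groups within a chromosome, and the splits of cells by the cluster absent from control 1 and by a Cdkn1a UMI, were chosen only after the results were seen, and the tests of chromosome balance in whole classes, of random gene groups, of neighbouring genes and of G2/M were written before. In mutant mesenchyme more cells had an autosome whose summed expression was off by at least 35%. The share was 5.39% in control 1 (95% interval 3.66% to 7.60%), 16.1% in mutant 1 (13.8% to 18.5%) and 10.8% in mutant 2 (9.41% to 12.3%). Ectoderm gave 12.2%, 11.5% and 11.7%, endothelium 3.12%, 4.04% and 4.05%, erythroid cells 7.27%, 2.68% and 4.28%, and flank 12.6%, 15.8% and 11.8%. Among mutant mesenchyme cells the imbalance went with Cdkn1a, with 56.2% of the cells with a Cdkn1a UMI off in mutant 1 and 47.8% in mutant 2, against 9.59% and 5.13% of the cells without one. By another measure, a chromosome off by at least 30% in both of its sets of alternate genes, 1.80% of mesenchyme cells of control 1, 12.9% of mutant 1 and 8.78% of mutant 2 were affected. It gave 5.92%, 8.53% and 6.25% in ectoderm, 7.32%, 12.1% and 7.35% in flank, 1.04%, 1.01% and 1.90% in endothelium and 3.26%, 1.01% and 2.93% in erythroid cells, so the mutant mesenchyme differs from its own control more than from ectoderm or flank. The alternate sets of a chromosome had mean correlations across cells of 0.114, 0.516 and 0.482 in all mesenchyme. In flank these correlations were 0.187, 0.273 and 0.480, and in ectoderm 0.188, 0.168 and 0.163. The chromosome-wide pattern was therefore not confined to mesenchyme, as flank of mutant 2 came close to mesenchyme of mutant 2. Every autosome was among those off in these 289 mutant cells, from 11.4% of the cells for chromosome 17 to 31.8% for chromosome 18.

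Mesenchyme cells of the mutants with a Cdkn1a UMI also carried other genes. Ano3 UMIs were in 72.3% of them in mutant 1 and 72.7% in mutant 2, against 4.85% and 3.06% of cells without a Cdkn1a UMI. Mdm2 UMIs were in 77.4% and 76.3%, against 37.5% and 34.7%, and Esco2 UMIs in 38.7% and 29.0%, against 17.4% and 18.8%. CRE UMIs were in 0 of 137 and 0 of 245 of them at equal depth, at which few mesenchyme cells had one.

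The chromosome imbalance is a candidate explanation of the p53 signal, as loss of cohesion can lead to missegregated chromosomes, and the lower of the mutant shares, 10.8%, lies above the interval of the control. Without the mesenchyme cluster absent from control 1 the shares were 9.43% in mutant 1 and 5.15% in mutant 2, and in that cluster they were 67.9% and 58.2%. Spread between cells without regard to chromosomes is argued against by random gene groups of the same sizes, whose alternate sets had a correlation of at most -0.0363 across cells of that cluster in the mutants, where those of chromosomes had 0.828 and 0.817. Neighbouring genes moving together are argued against by the correlation of proximal with distal genes of a chromosome, at least 0.729 in the same cells. Expression does not count chromosomes, and with 1 control library a gain or loss of chromosomes through the loss of Esco2 remains a hypothesis, which a DNA-based count of chromosomes in single cells would test.

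Of the cells with a Cdkn1a UMI 58.4% in mutant 1 and 64.5% in mutant 2 scored as G2/M, against 72.1% and 71.1% of cells without one, and 40.9% and 34.3% scored as S phase, against 27.1% and 28.5%. At most 1.22% of any of these groups scored as G1, so the scores only split S from G2/M, and arrest in G2/M cannot be told apart from cycling.

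In mesenchyme of control 1, mutant 1 and mutant 2, endothelial markers summed to 32.6, 40.3 and 40.6 CPM, erythroid markers to 600.1, 557.3 and 532.3 CPM, coelomic markers to 11.7, 9.83 and 4.33 CPM, surface ectoderm markers to 6.46, 15.0 and 8.65 CPM, and limb mesenchyme markers to 2612, 3052 and 2426 CPM.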
